A study of Arabidopsis thaliana with 36 samples.

How the data were processed

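Arabidopsis seedlings of 5 days, grown in continuous white light at 22 °C on half-strength medium per the labels, were sampled in 36 mRNA-seq libraries: WT and pif4pif5 at 1, 6 and 24 h (24 libraries) and WT, PIF4ox and PIF5ox at 16 h (12 libraries), each in LBL or WL. The authors aligned reads to TAIR10 with TopHat2 2.0.8b after base calling with CASAVA 1.8.2 and computed gene FPKM with Cufflinks 2.1.1; the deposited tables hold FPKM for 33557 genes per library. Values whose status was given as failed (43 values in 13 genes) were set to missing, and 33 genes listed as having too few reads were kept at their given value. The confidence limits of each FPKM were not used, and raw reads were not analysed here. Symbols came from the TAIR10.1 annotation, which held 32810 of the 33557 locus IDs and gave 10647 of them a symbol other than the locus; positions are those of the deposited tables with the start moved by 1 base. Libraries are unstranded, so overlapping and antisense genes are not told apart.

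Depth was estimated from the spacing of the smallest FPKM values in 8994 genes with a single transcript of at least 1500 bases, and a count model was not used because the tables hold no counts. FPKM sums were 891012 to 981259 per library. Replicates correlated at 0.974 to 0.989 (log2), and neither replicate of a group was a copy of the other. Groups came from the labels.

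Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, separately for the time course and the 16 h experiment, and with empirical Bayes moderation that follows the trend of variance with level. Genes with FPKM of at least 1 in at least 2 libraries were tested (20843 and 20447 genes; 12 and 6 residual degrees of freedom). Every p for a gene is from limma and every adjusted p is Benjamini-Hochberg within a comparison, called under 0.05. Comparisons were LBL against WL in each line and time, line against WT in each light, and their interactions; the pif4pif5 contrasts were also averaged over the 3 times. The 19 gene lists were tested with camera from limma at the preset correlation of 0.01 and again with the correlation estimated, adjusted over the lists: PIF family, photoreceptors, shade avoidance and PIF target genes, auxin response, cell wall loosening, gibberellin, brassinosteroid, flavonoid and anthocyanin synthesis, HY5 and COP1, light harvesting and RuBisCO, chlorophyll synthesis, circadian clock, sugar starvation and darkness, high light and oxidative stress, heat shock, jasmonate and wounding, cell cycle, root markers and stomatal lineage markers.

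The groups, contrasts, lists, main model and the rule for named genes were fixed before the data were examined. Named genes were PIF4 and PIF5 in every group; in each comparison with at least 10 calls, the 5 largest rises and 5 largest falls among called genes with a symbol whose libraries did not overlap (for averages, of the same sign at all 3 times); and up to 4 called members of each list. The LBL response of independently chosen genes was compared between genotypes with an exact permutation test. Overlaps of calls were compared with the number expected for independent calls. The gain lines share WT libraries, so 50 sets of libraries without any change, WT included, were simulated in the same design. Loss and gain were compared over genes called in the mutant, with exact binomial intervals.

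The pipeline was tested on simulated data with known changes, placed only in genes with a mean log2(FPKM + 1) above 1. The noise was normal, independent between libraries and of the fitted spread, so the values below hold only under these conditions. Changes of 1 log2 unit were recovered in 97.0% of genes for LBL in WT at 6 h, 95.5% for the 6 h interaction, 83.6% for PIF4ox against WT in WL and 65.7% for the PIF4ox interaction; changes of 0.5 were recovered in 74.6%, 47.8%, 32.8% and 8.96%. False calls were 3.86% to 6.61% of calls. Alternatives planned ahead were a pseudocount of 0.1, no filter, median-ratio scaling, a replicate block, no mean-variance trend, a separate fit of the compared groups, the estimated correlation, and leaving out each library, where the lone library is assumed to vary like the other groups. Protein-coding genes only, averages without the 6 h libraries, and leaving out the libraries of low root markers were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.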

Results

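The data were transcript levels, as gene FPKM (fragments scaled by transcript length and library depth), from 36 mRNA-seq libraries of 5-day-old Arabidopsis thaliana Columbia seedlings. A time course of 24 libraries held wild type (WT) and the pif4-101 pif5-1 double mutant (pif4pif5), each moved to low blue light (LBL) or kept in mock white light (WL) for 1, 6 or 24 h. A separate experiment of 12 libraries held WT, 35S::PIF4-Flash (PIF4ox) and 35S::PIF5-Flash (PIF5ox) seedlings after 16 h of LBL or WL; these lines express an epitope-tagged PIF from a strong viral promoter. Each of the 18 groups had 2 libraries. PIF4 and PIF5 are phytochrome-interacting basic helix-loop-helix transcription factors of growth, and cryptochromes are the plant's blue-light receptors. The title of the series asks how these act together on growth when blue light is limiting. The files hold no fragment counts. The size of the smallest FPKM steps put the depth at 16.0 to 40.3 M fragments per library with a median of 21.9 M: 20.9 to 38.7 M at 1 h, 17.9 to 27.7 at 6 h, 16.0 to 40.3 at 16 h and 19.2 to 24.2 at 24 h. Between 18987 and 19870 genes reached an FPKM of 1 in a library. Changes are given as log2 differences of FPKM + 1 with their standard error, n = 2 libraries per group. The labels do not say whether replicates were grown separately, so the p-values measure only the spread between these samples.

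The 2 PIF genes were read in every group before anything else. PIF5 (AT3G59060, chromosome 3, 21827978 to 21830507, TAIR10) lay between 2.14 and 7.57 FPKM in the 12 libraries labelled pif4pif5 and between 21.2 and 48.4 FPKM in the 12 WT libraries of the time course. Its level in pif4pif5 was lower by a log2 difference of -2.66 ± 0.05 in WL and -2.79 ± 0.05 in LBL, averaged over the times. PIF4 (AT2G43010, chromosome 2, 17886427 to 17889050) goes against the label at gene level: it lay between 8.30 and 25.0 FPKM in the libraries labelled pif4pif5 and between 6.85 and 32.7 FPKM in WT. In pif4pif5 it was higher than in WT in WL, by 0.30 ± 0.06 (limma, adjusted p = 0.018; the call ended without any 1 of 4 single WL libraries, at adjusted p = 0.0519 to 0.055), and not called in LBL, at -0.09 ± 0.06 (adjusted p = 0.42). A gene-level FPKM does not show where along the gene the reads fall. In PIF4ox, PIF4 stood at 224 ± 20 FPKM in WL and 379 ± 52 in LBL (SD, n = 2), against 8.60 and 43.8 in WT. In PIF5ox, PIF5 stood at 150 ± 19 FPKM in WL and 284 ± 60 in LBL, against 18.4 and 39.9 in WT. PIF4 was also higher in PIF5ox, at 52.9 FPKM in WL and 135 FPKM in LBL, by 2.48 ± 0.19 and 1.57 ± 0.19. PIF5 was higher in PIF4ox in WL, at 45.6 FPKM against 18.4 (1.21 ± 0.25; limma, adjusted p = 0.016), a call that ended without PIF4ox WL replicate 2 or WT WL replicate 2; in LBL it was not called.

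**Figure D1:**
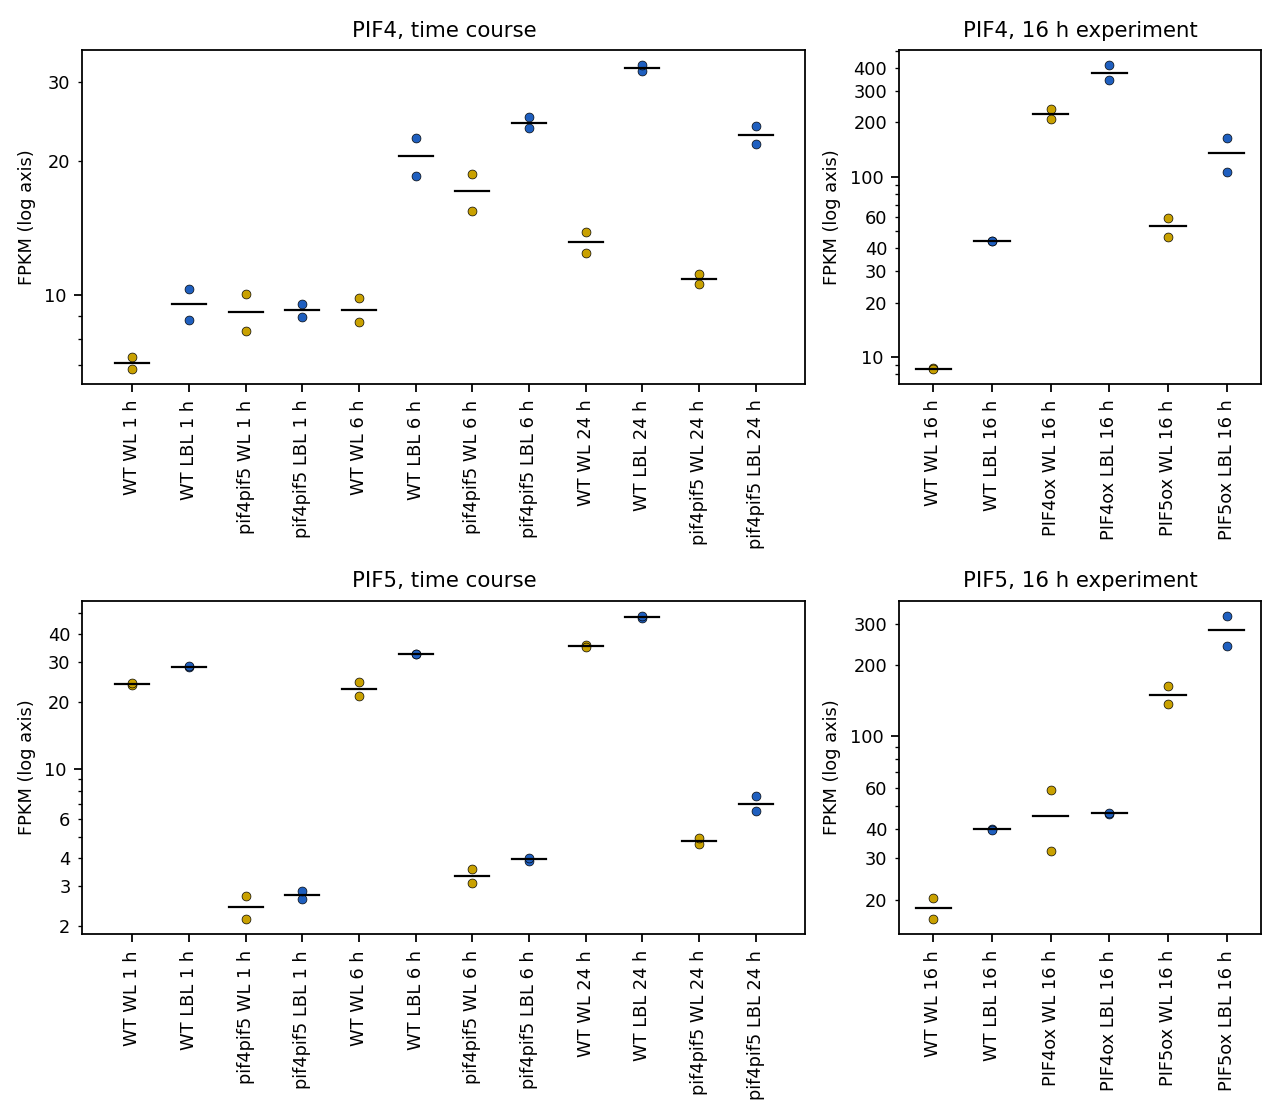
FPKM (log axis) of PIF4 and PIF5 in each library (points) with group means (lines), for the time course and the 16 h experiment; yellow is WL and blue is LBL. PIF5 in the pif4pif5 libraries (2.14 to 7.57 FPKM) lies below every WT library (21.2 to 48.4 FPKM), while PIF4 overlaps between the genotypes.

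Which transcripts respond to LBL in WT, and how soon, is the question of the next comparisons. After 1 h the genes of flavonoid and anthocyanin synthesis, the red and UV-shielding pigments of the seedling, fell together: 18 of 22 measured members fell and none rose (adjusted over the list alone, 21 fell). PAP1, a MYB activator of anthocyanin genes, fell by 2.08 ± 0.25, MYB12, a MYB activator of flavonol genes, by 1.03 ± 0.13 and TT7, a flavonoid hydroxylase, by 0.99 ± 0.12 on the log2 scale. Of the list around HY5 and COP1, a transcription factor of light responses and the ubiquitin ligase that removes it, 17 of 22 fell and 1 rose (18 and 1 adjusted over the list alone). Among them the light-stress protein gene ELIP1 dropped from 75.2 to 20.4 FPKM (-1.84 ± 0.12), BBX31 by -1.51 ± 0.16 and AT3G44450, a cryptochrome inhibitor gene, by -1.43 ± 0.10. Genes induced by darkness and sugar starvation rose in 10 of 16 members and fell in 1, with DIN10, a raffinose synthase gene, at 0.80 ± 0.13, the transcription factor gene BZIP1 at 0.62 ± 0.10 and TPS11 at 0.56 ± 0.09. Outside the lists, the largest rises were those of NIA1, a nitrate reductase gene (1.74 ± 0.10), the expansin gene EXPA16 (1.69 ± 0.18) and the touch-induced calmodulin-like gene TCH3 (1.52 ± 0.13). The largest falls were in LSU2 and LSU3, induced by low sulfur (-2.79 ± 0.16 and -2.18 ± 0.21), TBL26, a trichome birefringence-like gene (-2.17 ± 0.14), and SQP1, a squalene monooxygenase-like gene (-2.01 ± 0.09).

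Also at 1 h, clock genes fell in 8 of 22 members (11 fell and 2 rose over the list alone), among them RVE1 (-0.59 ± 0.07) and AT5G64170 (-0.67 ± 0.12). High light and oxidative stress genes fell in 5 of 9, and the heat shock genes HSFA2, HSP90.1 and HSP101 fell by 0.78 ± 0.11, 0.76 ± 0.08 and 0.70 ± 0.07 among 6 measured. Stomatal lineage genes rose in 4 of 7, including TMM (0.37 ± 0.06). In the lists related to growth, shade avoidance and PIF target genes rose in 4 of 18, auxin response genes in 5 of 23, and cell wall loosening genes in 3 of 21 with 3 falling. Brassinosteroid genes rose in 5 of 16 with 2 falling, and gibberellin genes in 3 of 18 with 1 falling. The lists that passed the set test (limma camera, adjusted p over 19 lists) were flavonoid (2.3e-25; adjusted p = 0.015 with an estimated correlation), HY5 and COP1 (2.1e-16; 0.0063 likewise), clock (1.8e-05; 0.0070), high light (1.9e-05; 0.013) and heat shock (7.3e-05; 0.0070). The calls for starvation (9.0e-05), stomatal lineage (0.017) and jasmonate (0.038; 1 of 13 rose and 2 fell) were lost, at adjusted p = 0.25, 0.097 and 0.51 with an estimated correlation; jasmonate also lost its call under median-ratio scaling. In all, 3707 of 20842 genes tested changed at 1 h, 2349 higher and 1358 lower. Under median-ratio scaling the split turned, with 1021 higher and 2011 lower, so the balance of rises and falls is not fixed by these data. Leaving out any 1 of the 4 libraries brought the count to 1683 (WT LBL replicate 2), 2063 and 2139 (WT WL replicates 2 and 1) or 2118 (WT LBL replicate 1).

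By 6 h every one of the 22 measured flavonoid genes had fallen in WT. DFR, dihydroflavonol reductase, went from 180 to 12.6 FPKM (-3.79 ± 0.29), LDOX from 170 to 12.7 (-3.66 ± 0.24) and TT7 from 53.0 to 3.18 (-3.70 ± 0.12). Starvation genes rose in 14 of 16, with DIN1, a senescence-associated gene, going from 1.1 to 66.5 FPKM (5.01 ± 0.58), BT2 by 2.39 ± 0.12 and DIN10 by 2.00 ± 0.13. HY5 and COP1 list genes fell in 18 of 22 and rose in 1, with AT3G44450 at -3.12 ± 0.10 and ELIP1 at -2.91 ± 0.12. Genes of the lists related to growth were called in both directions: of 21 cell wall loosening genes 14 rose, such as the expansin gene EXPA8 (1.24 ± 0.11) and the xyloglucan endotransglucosylase gene XTH19 (1.15 ± 0.07), and 5 fell, such as XTH31 (-1.10 ± 0.07). Shade avoidance and PIF target genes rose in 10 of 18 and none fell, with PAR1, a bHLH repressor gene of shade responses, at 1.13 ± 0.13 and XTH15 at 0.81 ± 0.08. Brassinosteroid genes rose in 12 of 16, with CPD, a brassinosteroid synthesis enzyme, at 0.82 ± 0.05, and gibberellin genes in 9 of 18, with GASA6, a gibberellin-regulated peptide, going from 62.0 to 426 FPKM (2.75 ± 0.11); 3 gibberellin genes fell, with the synthesis gene GA3OX2 at -0.99 ± 0.16. PIF4 rose by 1.06 ± 0.11 and PIF5 by 0.51 ± 0.08, while the PIF relative UNE10 fell by 1.25 ± 0.07. Among photoreceptors PHYA rose by 0.71 ± 0.04, CRY2 by 0.70 ± 0.04 and CRY1 by 0.51 ± 0.04. The test called flavonoid (adjusted p = 1.9e-29; 0.022 with an estimated correlation), HY5 and COP1 (3.0e-13; 0.015), starvation (1.1e-08) and brassinosteroid (0.035); the last 2 were lost at adjusted p = 0.14 and 0.37 with an estimated correlation. Shade avoidance (adjusted p = 0.062) and cell wall loosening (0.10) missed the threshold.

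At 24 h the pigment gene DFR and the light-stress gene ELIP1 showed larger falls. DFR was at 2.2 FPKM against 87.1 in WL (-4.76 ± 0.29) and ELIP1 at 4.12 against 156 (-4.93 ± 0.12). Among the named genes the largest fall was in the thionin gene THI2.2, a defence peptide, at 3.26 against 155 (-5.20 ± 0.16). All 22 flavonoid genes and 19 of 22 HY5 and COP1 list genes fell (1 rose), and 15 of 16 starvation genes rose. Jasmonate and wounding genes fell in 7 of 13 and rose in 2, with the vegetative storage protein gene VSP2 at -2.89 ± 0.30 and the lipoxygenase gene LOX2 at -1.50 ± 0.17. Auxin response genes rose in 14 of 23, with GH3.2, an auxin-conjugating enzyme, at 1.28 ± 0.10 and IAA29 at 0.99 ± 0.17. Root marker genes moved with LBL too: 10 of 16 rose and 2 fell in WT (list adjusted p = 0.16), with a marker mean (log2) of 3.66 and 3.72 in the LBL libraries against 3.21 and 3.24 in WL. In pif4pif5 the means were 3.55 and 3.56 against 3.25 and 3.19, and at 6 h 9 of 16 rose in WT. Shade avoidance and PIF target genes rose in 12 of 18 and fell in 1, with FHL, a helper of phytochrome A import, at 1.03 ± 0.15 and ATHB2, a shade-induced homeobox gene, at 0.79 ± 0.10. Members of the light harvesting and RuBisCO list moved apart: LHCB1.4 rose by 3.07 ± 0.10 and LHCB1.3 by 1.61 ± 0.07, while LHCB4.3 fell by 3.84 ± 0.13 and RBCS3B by 1.70 ± 0.06. Reads of these near-identical paralogs are hard to assign. In chlorophyll synthesis, PORA, the protochlorophyllide reductase of dark-grown seedlings, reached 7.68 FPKM against 0.0678 in WL (3.03 ± 0.10), and PORB rose by 2.18 ± 0.05. The test called flavonoid (adjusted p = 3.3e-26; 0.033 with an estimated correlation), HY5 and COP1 (8.7e-15; 0.0098), starvation (0.00017), jasmonate (0.0029) and heat shock (0.029). The last 3 were lost at adjusted p = 0.27, 0.27 and 0.12 with an estimated correlation, and heat shock also under median-ratio scaling. Shade avoidance and auxin response were at adjusted p = 0.071 and 0.085.

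Over all genes, 9153 changed at 6 h in WT (6077 higher, 3076 lower) and 12213 at 24 h (8894 higher, 3319 lower). Median-ratio scaling gave 3940 higher and 4393 lower at 6 h, and 5006 higher and 5300 lower at 24 h, where it moved the median of all genes by -0.154. The excess of rises in the main counts therefore rests on the deposited scaling. It also turned the balance of the light harvesting list at 1 and 24 h (1 rose and 4 fell; 7 rose and 9 fell) and of the clock list at 24 h (7 rose and 10 fell). Of genes called at 6 and 24 h, 5004 were higher at both and 2246 lower at both (2593 and 490 if independent), and 168 changed direction; the WL and LBL libraries of each time are separate.

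**Figure D2:**
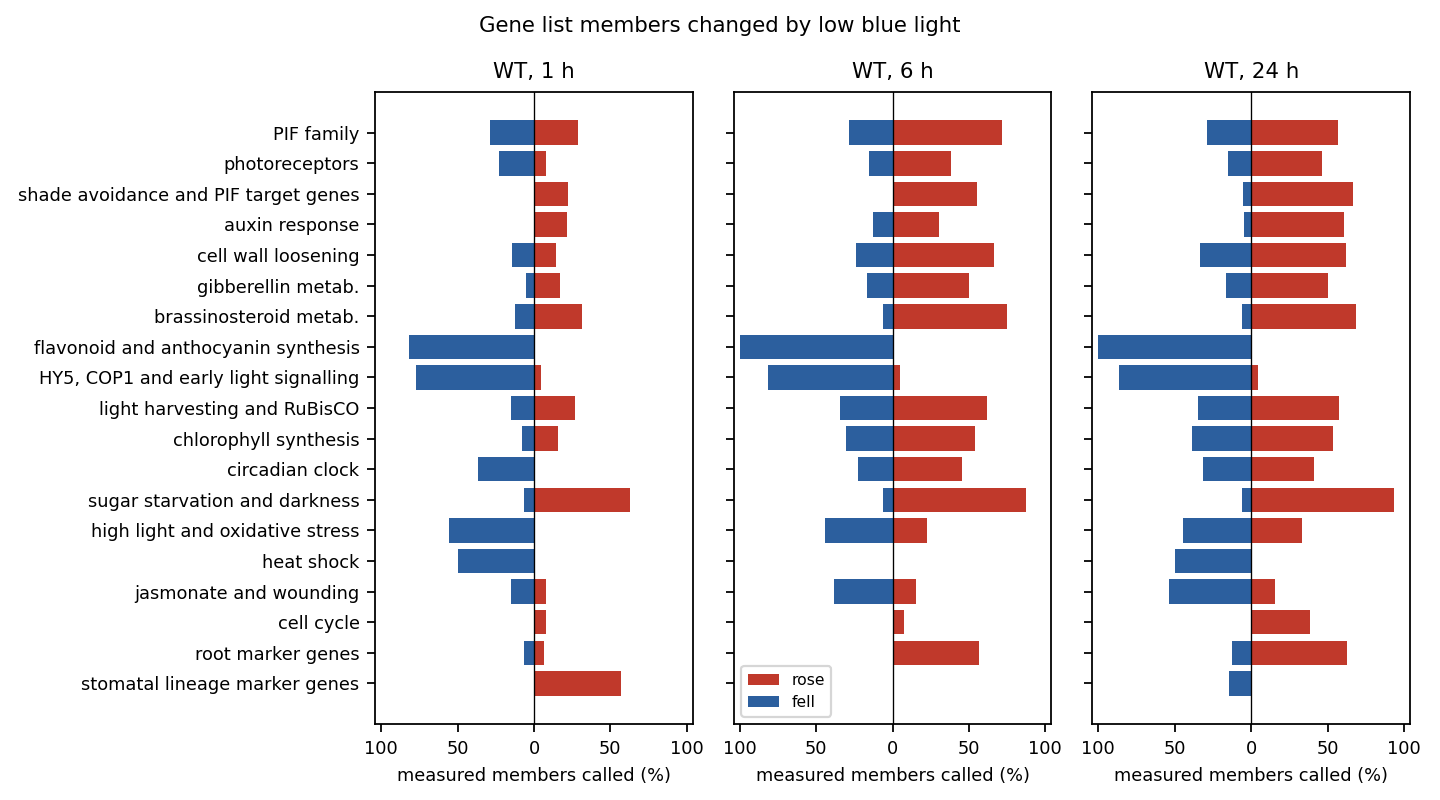
Share of measured members of each gene list (%) that rose (red, to the right) or fell (blue, to the left) with LBL in WT at 1, 6 and 24 h, adjusted p under 0.05 over all genes. Flavonoid synthesis genes fell in 18, 22 and 22 of 22 members; under median-ratio scaling the balance of light harvesting and chlorophyll synthesis turned at 1 and 24 h, and that of the clock and the cell cycle at 24 h.

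The same comparison in pif4pif5 shows what LBL did in the mutant. Of 22 flavonoid genes 17 fell at 1 h, and all 22 at 6 and 24 h, with DFR at -3.93 ± 0.29 and -4.63 ± 0.29 at the later times; PAL2, a phenylalanine ammonia-lyase gene, fell less than in WT at 24 h (interaction 0.40 ± 0.07, a call that ended without any 1 of 3 single libraries). HY5 and COP1 list genes fell in 13, 20 and 16 of 22, with ELIP1 at -1.95 ± 0.12, -3.26 ± 0.12 and -4.89 ± 0.12. Starvation genes rose in 7, 13 and 15 of 16, and BT2 rose by 0.76 ± 0.12, 2.17 ± 0.12 and 1.8 ± 0.12. GASA6 rose at each time too, by 1.09 ± 0.11, 2.68 ± 0.11 and 3.02 ± 0.11. PIF4 rose at 6 h by 0.49 ± 0.11 and at 24 h by 1.00 ± 0.11; its value at 1 h was 0.01 ± 0.11. Clock genes fell in 8 of 22 at 1 h, with GI at -0.81 ± 0.10, and high light genes in 6 of 9 at 6 h. Shade avoidance and PIF target genes rose in 2, 9 and 8 of 18, with XTH15 at 0.66 ± 0.08 and 0.93 ± 0.08 at 6 and 24 h; at 1 h scaling leaves 0 risen and 1 fallen. Cell cycle genes fell in 3 of 13 at 1 h. The set test called flavonoid and HY5 and COP1 at all 3 times, clock and heat shock at 1 h and high light at 1 and 6 h, each also with an estimated correlation (adjusted p = 0.0050 to 0.045). Calls for starvation at all 3 times were lost at adjusted p = 0.12, 0.27 and 0.23 with an estimated correlation, and that for the cell cycle at 1 h (0.0004) at adjusted p = 0.25. Brassinosteroid (adjusted p = 0.0062, 0.013 and 0.042) was lost at 0.22, 0.35 and 0.46, and jasmonate at 6 and 24 h (0.0062 and 0.033) at adjusted p = 0.35 and 0.46 with an estimated correlation. Heat shock genes at 24 h, 3 of 6 of which fell (0.029), were lost at adjusted p = 0.10 with an estimated correlation; they, brassinosteroid and jasmonate at 24 h lost their call under scaling too. Counts were 2885 genes at 1 h (1475 higher, 1410 lower), 9301 at 6 h (7024 and 2277) and 11235 at 24 h (7400 and 3835). Scaling gave 3549 higher and 3954 lower at 6 h (median shift -0.119) and 5201 and 5282 at 24 h. The 1 h count was 1407 without LBL replicate 1, 1597 without WL replicate 1 and 1268 without WL replicate 2. Genes called in both genotypes moved alike: at 24 h 6463 were higher in both and 2786 lower in both (3158 and 611 if independent), and 37 moved apart.

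Whether the LBL response differed between pif4pif5 and WT was tested as an interaction. At 1 h FRO7, a ferric reductase of chloroplasts, fell with LBL in WT from 20.2 to 10.4 FPKM and stayed at 15.4 in pif4pif5 (0.90 ± 0.11, adjusted p = 0.0034). HB51, a homeobox gene, went from 1.44 to 2.50 in WT and from 2.99 to 1.99 in pif4pif5 (-0.95 ± 0.12, adjusted p = 0.0034). At 6 h XTH19 rose from 17.5 to 39.9 FPKM in WT and from 14.3 to 22.2 in pif4pif5 (-0.55 ± 0.09, adjusted p = 0.020). HEMA1, the first enzyme of tetrapyrrole synthesis, rose by 0.47 ± 0.15 in WT and fell by 0.62 ± 0.15 in pif4pif5 (-1.09 ± 0.21, adjusted p = 0.034); SQP2 (-1.33 ± 0.21), ST4B (-1.41 ± 0.22) and XTH14 (-1.19 ± 0.15) also rose less or fell more in the mutant. At 24 h FRO6, another ferric reductase, had 1.23 ± 0.15 and ATSPS4F, a sucrose-phosphate synthase, 1.00 ± 0.12, while ELI3-1, a cinnamyl-alcohol dehydrogenase homolog, had -0.88 ± 0.07, CDKB2;1, a mitotic kinase, -0.35 ± 0.06 and the auxin-induced SAUR22 -2.03 ± 0.43. At 6 h bHLH38 had 1.99 ± 0.35 and NEET -1.65 ± 0.32. Averaged over the times, the largest positive values among genes with a symbol were those of M17 (1.62 ± 0.33), BHLH100 (1.19 ± 0.30) and BHLH101 (0.93 ± 0.19). AtMT4b (0.85 ± 0.20) and bHLH38 (0.84 ± 0.20) came next, and CLE14 was the most negative (-0.94 ± 0.24). Smaller in size, HB51 (-0.46 ± 0.07), XTH19 (-0.30 ± 0.05), EXPA11 (-0.38 ± 0.08) and PIF4 itself (-0.39 ± 0.09) were negative. RBCS1B (0.32 ± 0.04) and AT3G44450 (0.45 ± 0.08) were positive. Among the named genes, the calls of PIF4, XTH19, HEMA1, SAUR22, EXPA11, SQP2 and ST4B ended under at least 1 other setting or left-out library; those of FRO7, HB51 and XTH14 at their own time did not, save that a fit of the compared groups alone kept only FRO7.

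By list, shade avoidance and PIF target genes had negative interactions at 24 h (mean -0.25; adjusted p = 0.017) and on average (mean -0.16; adjusted p = 0.0074), with 0 of 18 members called and IAA29 and HFR1 at -0.63 ± 0.24 and -0.52 ± 0.18 at 24 h; limma gave 2 members adjusted over the list alone for the average. Cell cycle genes had negative interactions at 1 h, 24 h and on average (means -0.26, -0.24 and -0.16; adjusted p = 0.00016, 0.00039 and 5.8e-05), and CDKB2;1 was called each time. HY5 and COP1 list genes had positive ones at 24 h (2 of 22 called, 5 over the list alone; mean 0.22; adjusted p = 5.7e-07) and on average (adjusted p = 0.0032), and light harvesting genes at 24 h (1 of 26; adjusted p = 2.1e-06), where RCA, RuBisCO activase, had 0.35 ± 0.08, a call that ended under several other settings. At 6 h starvation and high light genes had negative ones (0 of 16 and 0 of 9 called by limma, 2 and 4 negative over the list alone; adjusted p = 0.00043 and 0.00092). None of these list calls held with the correlation estimated: adjusted p = 0.33 and 0.37 for shade avoidance, 0.64, 0.36 and 0.37 for the cell cycle, 0.14 and 0.37 for HY5 and COP1, 0.36 for light harvesting, 0.63 for starvation and 0.15 for high light. The counts were 419 genes at 1 h (136 positive, 283 negative), 140 at 6 h (81 and 59), 337 at 24 h (191 and 146) and 622 on average (393 and 229). Scaling gave 250 positive and 161 negative at 1 h, 57 and 64 at 6 h, 318 and 65 at 24 h, and 593 and 166 on average.

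These counts rest on single libraries. At 1 h the count was 14 and 179 without WT LBL replicates 2 and 1, 217 and 22 without WT WL replicates 1 and 2, 22 without pif4pif5 LBL replicate 1, and 150 and 15 without pif4pif5 WL replicates 1 and 2. At 6 h it was 26 and 232 without WT LBL replicates 1 and 2, 89 and 58 without WT WL replicates 1 and 2, 19 without pif4pif5 LBL replicate 2, and 5 and 229 without pif4pif5 WL replicates 1 and 2. At 24 h it was 119 and 177 without WT LBL replicates 1 and 2, 207 and 162 without WT WL replicates 1 and 2, and 111 and 144 without pif4pif5 LBL replicates 1 and 2. The averaged count was 351 without WT LBL replicate 2, 382 without WT WL replicate 2, 370 without pif4pif5 LBL replicate 1 and 324 without pif4pif5 WL replicate 2, all at 1 h, and 411 without WT WL replicate 2 at 6 h. Of genes called at 1 and 24 h, 39 were positive at both and 24 negative at both (1.25 and 1.98 if independent); the 6 h and 24 h calls shared 0 in the same direction (0.742 positive and 0.413 negative if independent), from 140 and 337 limma calls, and 2 in opposite directions. Averaging without the 6 h libraries, an alternative chosen after seeing the data, gave 1549 genes.

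**Figure D3:**
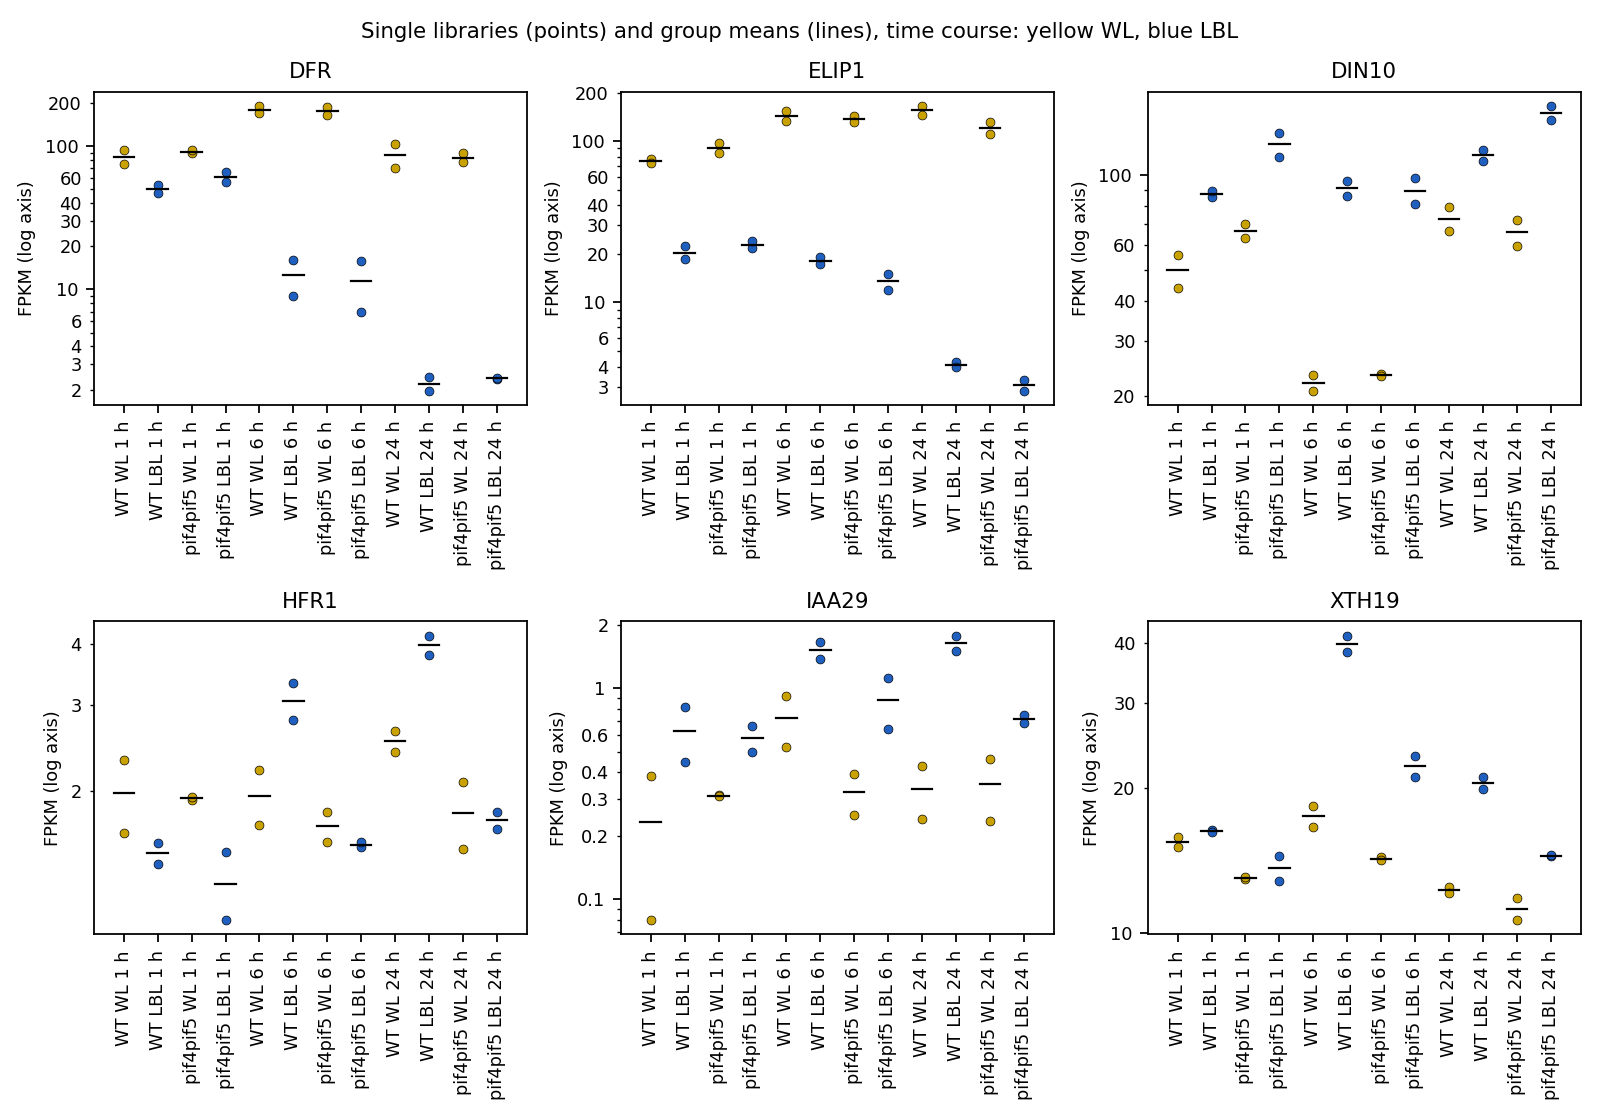
FPKM (log axis) of DFR, ELIP1, DIN10, HFR1, IAA29 and XTH19 in each library of the time course (points) with group means (lines); yellow is WL and blue is LBL. DFR fell to 2.2 FPKM in WT and 2.40 in pif4pif5 at 24 h of LBL, while XTH19 reached 39.9 FPKM in WT and 22.2 in pif4pif5 at 6 h.

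A second view compares the genotypes in each light, averaged over 1, 6 and 24 h. In LBL part of the shade avoidance, cell wall and auxin response lists was lower in pif4pif5. Of 18 shade avoidance and PIF target genes 6 were lower and none higher (7 lower adjusted over the list alone): HFR1, a bHLH brake on shade responses, by -0.55 ± 0.08, IAA19 by -0.32 ± 0.08, FHL by -0.35 ± 0.09 and IAA29 by -0.36 ± 0.10. Of these, only the call of HFR1 held under every other setting and left-out library. Of 21 cell wall loosening genes 10 were lower and 1 higher, with XTH19 at -0.51 ± 0.04, XTH17 at -0.49 ± 0.06, EXPA8 at -0.44 ± 0.06 and EXPA11 at -0.37 ± 0.05. SAUR19 and SAUR22, small auxin-induced growth genes with near-identical neighbours, were lower by -0.70 ± 0.13 and -0.84 ± 0.17 among 4 of 23 auxin response genes. Light harvesting genes were lower in 17 of 26 and higher in 6, with LHCB1.4 at -0.48 ± 0.06 and LHCB2.1 at -0.44 ± 0.05. Root marker genes were lower in 5 of 16 (7 over the list alone), such as the root hair expansin EXPA7 at -0.32 ± 0.07. Outside the lists, the thalianol pathway genes THAS1 and CYP708A2 were lower, by -1.15 ± 0.13 and -1.09 ± 0.15, and CYP706A6, a cytochrome P450 gene, was higher by 0.81 ± 0.04.

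In WL the shade avoidance list had no called member of 18 (limma; list adjusted p = 0.93), and 5 of 21 cell wall genes were lower, with EXPA8 at -0.69 ± 0.06 and XTH18 at -0.33 ± 0.04. Light harvesting genes were lower in 12 of 26 (17 over the list alone), with LHCB1.4 at -0.55 ± 0.06. The stomatal lineage genes SPCH, EPF2 and TMM were higher, by 0.34 ± 0.05, 0.34 ± 0.07 and 0.16 ± 0.03, among 7; the call of EPF2 ended under another setting or without 1 library. The test called light harvesting (adjusted p = 8.7e-11), stomatal lineage (0.00043), cell wall (0.0019), cell cycle (0.022, higher) and jasmonate (0.044, lower) in WL. In LBL it called cell wall (0.00073), light harvesting (0.0028), shade avoidance (0.0037), root markers (0.0063), cell cycle (0.0063, lower) and HY5 and COP1 (0.031, higher). None held with an estimated correlation: adjusted p = 0.20, 0.062, 0.20, 0.52 and 0.52 in WL, and 0.19, 0.44, 0.19, 0.19, 0.40 and 0.40 in LBL. In WL the jasmonate call also ended under median-ratio scaling. The PIF family list was lower in WL too (0.044; 0.20 with an estimated correlation), but it contains PIF5, which is mutated in this line. Counts were 971 genes in WL (421 higher, 550 lower) and 2368 in LBL (1131 and 1237; 1396 and 975 under median-ratio scaling). The WL count was 431 and 550 without WT replicate 2 and pif4pif5 replicate 1 at 1 h, 411 without pif4pif5 replicate 2 at 1 h, 618 and 539 without WT replicates 1 and 2 at 6 h, 486 without pif4pif5 replicate 2 at 6 h, and 537 without WT replicate 1 at 24 h. Without the 6 h libraries, chosen after seeing the data, the counts were 1662 in WL and 1332 in LBL. In both lights 90 genes were higher and 224 lower (22.8 and 32.6 if independent).

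The size of the LBL response was also scored in each time-course library with genes chosen outside it: the mean of 6446 genes called higher minus that of 3296 called lower by LBL in WT at 16 h. The response was 0.28 in WT and 0.23 in pif4pif5 at 1 h, 0.65 and 0.62 at 6 h, and 0.90 and 0.84 at 24 h. Averaged over the times it was 0.61 and 0.56, a difference of -0.0457 (two-sided exact permutation of genotype within time and light, p = 0.156). At single times the differences were -0.0411, -0.0353 and -0.0607 (exact p = 0.0556, 0.5 and 0.444), and 36 permutations cannot give a p under 0.0556. The difference was not past the threshold at any time, and with 2 libraries per group no single time could pass it.

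The 16 h experiment gave the LBL response of WT again, beside that of the gain lines. WT LBL replicate 2 was poor in root transcripts, with a root marker mean (log2) of 2.16 against 3.07 in replicate 1. In WT all 22 flavonoid genes fell, with DFR from 122 to 0.53 FPKM (-6.34 ± 0.21), LDOX by -5.82 ± 0.21 and TT19, a pigment transport gene, by -5.31 ± 0.33. Starvation genes rose in 14 of 17 and none fell, with DIN1 at 6.15 ± 0.38, DIN6, an asparagine synthetase gene, at 3.21 ± 0.25 and TPS11 at 2.45 ± 0.11. HY5 and COP1 list genes fell in 13 of 22 and rose in 2, with AT3G44450 at -4.66 ± 0.20, and jasmonate genes fell in 7 of 13, with LOX2 at -2.33 ± 0.21. PIF4 rose from 8.60 to 43.8 FPKM (2.22 ± 0.19) and PIF5 from 18.4 to 39.9 (1.08 ± 0.25). CPD rose by 1.45 ± 0.06, IAA29 by 1.62 ± 0.17, HFR1 by 1.33 ± 0.18 and the clock gene RVE4 by 1.67 ± 0.07. In PIF4ox 21 of 22 flavonoid genes fell, led by chalcone synthase TT4 (-4.39 ± 0.20), 15 of 17 starvation genes rose and 14 of 18 shade avoidance and PIF target genes rose (1 fell), such as ST2A at 2.34 ± 0.26. In PIF5ox 21 of 22 flavonoid genes fell, 15 of 17 starvation genes rose and 17 of 18 shade avoidance genes rose, with ST2A at 3.15 ± 0.26, PAR1 at 2.76 ± 0.16 and IAA29 at 2.53 ± 0.17. Auxin response genes rose in 15 of 22 and brassinosteroid genes in 12 of 16 in PIF5ox, while cell cycle genes fell in 6 of 13, stomatal lineage genes in 4 of 7 and jasmonate genes in 9 of 13.

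With an estimated correlation the flavonoid calls stood at adjusted p = 0.045 in WT, 0.059 in PIF4ox and 0.049 in PIF5ox, and the starvation calls at the same 3 values, so that those in PIF4ox were lost; with the preset one the largest of these was 3.4e-07. Calls lost with an estimated correlation were HY5 and COP1 in the 3 lines (adjusted p = 0.26, 0.30 and 0.23) and jasmonate (adjusted p = 0.39, 0.37 and 0.23). High light was lost too (adjusted p = 0.26, 0.30 and 0.23), as were brassinosteroid, shade avoidance and auxin response in PIF4ox (adjusted p = 0.31, 0.37 and 0.37), and these and the cell cycle in PIF5ox (adjusted p = 0.23, 0.23, 0.23 and 0.49). High light in PIF5ox also lost its call under median-ratio scaling, and auxin response in PIF4ox with a pseudocount of 0.1. The counts were 9795 of 20446 genes in WT (6487 higher, 3308 lower), 10253 in PIF4ox (6208 and 4045) and 10964 in PIF5ox (6959 and 4005). Median-ratio scaling gave 4382 and 4697 in WT, 4868 and 5058 in PIF4ox, and 5214 and 5354 in PIF5ox, with median shifts of -0.125 in WT and -0.114 in PIF5ox. Of the genes called in WT at 16 and 24 h, from separate experiments, 5257 were higher and 2307 lower in both (2787 and 536 if independent), and 129 moved apart.

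What more PIF4 does at the transcript level is asked by PIF4ox against WT in each light. In WL PIF5 was higher in this line too (1.21 ± 0.25), a call that rested on single libraries. In WL the shade avoidance and PIF target genes stood higher in 13 of 18 members and lower in none (15 over the list alone). HFR1 was at 49.1 FPKM against 1.4 (4.37 ± 0.18), ST2A, a jasmonate sulfotransferase, at 19.5 against 1.25 (3.19 ± 0.26), and PIL1, a PIF-like shade gene, at 12.8 against 0.824 (2.90 ± 0.24). Auxin response genes were higher in 18 of 22, with SAUR22 at 3.33 ± 0.20, IAA29 at 3.08 ± 0.17 and SAUR23 at 2.56 ± 0.14. Brassinosteroid genes were higher in 12 of 16, with the brassinolide-forming BR6OX2 at 0.99 ± 0.09 and CPD at 0.86 ± 0.06. Flavonoid genes were lower in 17 of 22 (20 over the list alone), with DFR at -2.22 ± 0.21 and UF3GT at -1.86 ± 0.11. Clock genes were higher in 8 of 22, with PRR7 at 1.37 ± 0.22, and chlorophyll synthesis genes lower in 4 of 13, with HEMA1 at -1.19 ± 0.24. PHYA was higher by 1.15 ± 0.09 and GASA6 by 2.38 ± 0.18; the zinc-finger gene OZF2 (3.92 ± 0.17) and the myrosinase-binding MBP1 (3.70 ± 0.25) were among the largest rises, and CYP97B3 (-2.68 ± 0.07) and GASA5 (-2.63 ± 0.27) among the largest falls. Of 14 root markers PHO1 (1.39 ± 0.16) and HKT1 (1.34 ± 0.14) were higher and NRT2.1 (-1.12 ± 0.23) lower. The root marker mean (log2) was 3.04 and 3.08 in the PIF4ox WL libraries and 2.82 and 2.65 in the WT WL libraries. Whether root content accounts for these differences was not tested. PIF4ox WL replicate 2 stood apart in seed-type genes, with a mean (log2) of 1.93 against 0.596 in replicate 1 and the seed storage gene CRA1 at 74.5 against 0.32 FPKM. The calls for auxin (adjusted p = 6.4e-14) and flavonoid (1.6e-19) held with the correlation estimated (adjusted p = 0.035 each). Those for shade avoidance (4.2e-11), brassinosteroid (6.3e-07) and clock (0.0026) did not, at adjusted p = 0.087 each with an estimated correlation, nor did chlorophyll (2.9e-05), at adjusted p = 0.28. The count was 3106 genes (2373 higher, 733 lower; 1246 and 1057 under scaling), and 1597, 915 and 1574 without PIF4ox WL replicates 1 and 2 and WT WL replicate 1.

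In LBL the cold-induced COR15A and COR15B stood at 328 and 338.5 FPKM in PIF4ox against 3.72 and 9.43 in WT (6.11 ± 0.28 and 5.01 ± 0.19), ST2A at 108 against 2.71 (4.83 ± 0.26), and GASA5 at 0.16 against 42.1 (-5.22 ± 0.27). Shade avoidance and PIF target genes were higher in 15 of 18, auxin response genes in 18 of 22 and brassinosteroid genes in 11 of 16 (1 lower). Cell wall loosening genes were higher in 12 of 21 and lower in 4, with XTH17 at 3.45 ± 0.41 and XTH30 at 2.02 ± 0.26. Chlorophyll synthesis genes were lower in 10 of 13, with PCB2 at -0.73 ± 0.11 and CHLM at -0.62 ± 0.06, and cell cycle genes in 5 of 13. Jasmonate genes were higher in 6 of 13, with LOX2 at 1.65 ± 0.21, whereas the glucosinolate-cleaving myrosinase gene TGG2 was lower by -2.92 ± 0.32. Root marker genes moved with this contrast: 5 of 14 were higher and 1 lower, with the endodermal genes CASP5 and CASP2 at 2.56 ± 0.44 and 2.31 ± 0.44. WT LBL replicate 2 was poor in root transcripts, with a marker mean of 2.16 (log2) against 3.07 in replicate 1, and IRT1, an iron transporter of roots, at 0.677 against 23.2 FPKM. Without that library 4 root markers were higher and 0 lower of the 14 tested with limma.

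Set tests in LBL called shade avoidance and auxin response (adjusted p = 2.7e-12 each), chlorophyll (1.8e-06), brassinosteroid (2.3e-06), cell cycle (0.0016), cell wall (0.0055), jasmonate (0.0099) and root markers (0.047). All were lost: adjusted p = 0.15, 0.068, 0.26, 0.19, 0.40, 0.28, 0.38 and 0.47 with an estimated correlation. The root marker call also ended with a pseudocount of 0.1 and without the filter. Flavonoid genes, lower in 4 of 22 (adjusted p = 0.033; 0.40 with an estimated correlation), lost their call under scaling. The count was 5423 (3219 higher, 2204 lower; 2665 and 2747 under scaling), 2461 without PIF4ox LBL replicate 1 and 2517 without WT LBL replicate 2. It was 2638 without both libraries of low root markers (WT LBL replicate 2 and PIF5ox WL replicate 2), an alternative chosen after seeing the data.

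The same was asked of PIF5ox. PIF4 was higher in this line too (2.48 ± 0.19 in WL), so its differences from WT cannot be assigned to PIF5 alone. In WL, PIF5ox had higher shade avoidance genes in 8 of 18 (11 over the list alone), with HFR1 at 3.41 ± 0.18, PIL1 at 2.17 ± 0.24 and IAA29 at 1.75 ± 0.17. Auxin response genes were higher in 7 of 22 (16 over the list alone), with SAUR22 at 2.12 ± 0.20, and flavonoid genes lower in 8 of 22 (18 over the list alone), with TT7 at -1.17 ± 0.18 and UF3GT at -1.0 ± 0.11, calls that ended under another setting or without 1 library. In LBL shade avoidance genes were higher in 16 of 18, with ST2A at 4.31 ± 0.26, HFR1 at 3.87 ± 0.18 and PIL1 at 3.51 ± 0.24. Auxin response genes were higher in 17 of 22, with IAA29 at 2.67 ± 0.17 and IAA19 at 2.51 ± 0.17, brassinosteroid genes in 11 of 16, with BR6OX2 at 1.27 ± 0.09, and photoreceptors in 4 of 13, with PHYA at 1.42 ± 0.09. Cell wall loosening genes were higher in 9 of 21 and lower in 3, with XTH17 at 2.90 ± 0.41. Flavonoid genes were lower in 8 of 22, with the chalcone synthase TT4 at -1.76 ± 0.20 and the flavonol synthase FLS1 at -1.63 ± 0.15, and chlorophyll synthesis genes in 9 of 13, with PCB2 at -0.74 ± 0.11. COR15A stood at 213 FPKM against 3.72 (5.50 ± 0.28). Root markers were higher in 3 of 14; without WT LBL replicate 2 none of the 14 was called by limma. The list calls in WL (adjusted p = 6.3e-09, 4.5e-10 and 6.0e-22 for shade avoidance, auxin and flavonoid) were lost at adjusted p = 0.20, 0.056 and 0.053 with an estimated correlation. Those in LBL (2.2e-15, 4.9e-13, 1.1e-06, 0.00076, 0.0067, 3.0e-05 and 1.1e-08 in the order given) were lost at adjusted p = 0.085, 0.059, 0.17, 0.17, 0.24, 0.17 and 0.17. Counts were 603 genes in WL (425 higher, 178 lower; 264 and 204 under scaling) and 3467 in LBL (2356 and 1111; 1604 and 1609 under scaling). The WL count was 166 and 270 without PIF5ox replicates 1 and 2, and 113 without WT replicate 1. The LBL count was 1612 and 624 without PIF5ox replicates 1 and 2, and 812 without WT replicate 2. In WL the root markers HKT1 and PHO1 were called higher, by 0.91 ± 0.14 and 0.78 ± 0.16, calls that ended under another setting or without 1 library. The WT WL libraries had root marker means (log2) of 2.82 and 2.65, and both were kept in the alternative below. PIF5ox WL replicate 2 was also low in root markers, with a mean of 2.61 (log2) against 3.19 in replicate 1. Without both libraries of low root markers (this one and WT LBL replicate 2), chosen after seeing the data, the counts were 222 and 839.

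The gain lines were set side by side. In LBL 2005 genes were higher in both and 981 lower in both, and in WL 391 and 154; 0 were called in opposite directions by limma in either light. COR15A, ST2A, HFR1, PIL1 and IAA29 were higher in both lines, and GASA5 lower in both, in LBL. Both contrasts use the same WT libraries, which alone makes them alike. The lines are also not separate gains of PIF4 and PIF5. PIF4 was higher in PIF5ox in both lights (2.48 ± 0.19 in WL). PIF5 was higher in PIF4ox in WL (1.21 ± 0.25), a call that rested on single libraries. The overlap therefore cannot be divided between the 2 factors. Independent calls would give 371 and 120 in LBL, and 49.3 and 6.38 in WL. In 50 simulations of libraries without any change, WT included, the mean of genes higher in both was 0 in LBL and 0.02 in WL. With no gene changed almost none is called, so these means do not show how far shared controls raise the overlap. Across genes, which are not independent replicates, the covariance of the fold changes was 0.173 in LBL and 0.116 in WL, against a simulated 0.0303 and 0.0298. Part of the excess over independent calls may come from the shared controls.

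Light by line interactions asked whether a gain line answered LBL differently from WT. In PIF4ox 6 of 22 flavonoid genes had a positive interaction (12 over the list alone, with 1 negative), with DFR at 2.35 ± 0.30, UF3GT at 2.00 ± 0.15 and PAP1 at 1.95 ± 0.26. DFR was near 0 in LBL in both lines (0.53 FPKM in WT, 0.685 in PIF4ox), so its interaction mostly restates the WL difference. UF3GT was lower in PIF4ox in WL by nearly the size of its interaction, so the same holds for it. How far low levels in LBL set the interaction of the whole list was not tested. GASA6 had -2.22 ± 0.26, GASA5 -2.59 ± 0.38 and the HY5 gene -0.64 ± 0.10. COR15A had 2.50 ± 0.40 and the cold-induced KIN1 4.76 ± 0.64. Each of these calls ended under at least 1 other setting or left-out library. The flavonoid call (adjusted p = 1.1e-10) was lost at adjusted p = 0.28 with an estimated correlation. The count was 105 (63 positive, 42 negative). It was 23 and 60 without PIF4ox LBL replicates 1 and 2, 11 and 31 without PIF4ox WL replicates 1 and 2, 29 and 6 without WT LBL replicates 1 and 2, and 36 and 57 without WT WL replicates 1 and 2. It was 0 without both libraries of low root markers, in limma. In PIF5ox, shade avoidance and auxin response genes had positive interactions (means 0.97 and 0.53), with 0 of 18 and 0 of 22 called by limma over all genes but 14 and 12 over the list alone. ST2A was at 2.44 ± 0.36, XTH15 at 1.84 ± 0.44 and IAA19 at 1.33 ± 0.24. The set test gave adjusted p = 7.4e-13 and 6.8e-08, both lost at adjusted p = 0.13 with an estimated correlation. Chlorophyll synthesis genes had a negative mean of -0.38 (6 of 13 negative over the list alone; adjusted p = 6.7e-06; 0.36 with an estimated correlation). Only 4 genes passed over all genes in limma, while 3138 had an unadjusted p under 0.05. They were ACS8, an ethylene synthesis gene (1.81 ± 0.18), AT5G61660 (0.69 ± 0.06), AT1G03495 (1.15 ± 0.12) and AT1G34041, which was listed at 0 in both PIF5ox LBL libraries and in every WT library at 16 h. These names were chosen after their values were seen. The PIF5ox count was 58 without WT WL replicate 2, 0 without WT LBL replicate 2, 2 without PIF5ox LBL replicate 2, and 1 without any other of the 8 libraries.

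The mutant and the gain lines were compared across the 2 experiments, which share no libraries. Loss here means the libraries labelled pif4pif5, in which PIF5 was lower at transcript level and PIF4 was not (-0.09 ± 0.06 in LBL). Of 2329 genes that differed between pif4pif5 and WT in LBL and were tested at 16 h, 1725 had the opposite sign in PIF4ox and 1727 in PIF5ox. The same sign was thus seen in 25.9% (exact binomial 95% interval 24.2 to 27.8) and 25.8% (24.1 to 27.7), against 40.8% and 40.5% of all tested genes. Genes are not independent, so the intervals are too narrow. Every shade avoidance gene called in both, 5 of 5, was lower in loss and higher in gain: HFR1, IAA29, IAA19, FHL and, with PIF4ox, PAR2. The 4 auxin response genes called in both (IAA19, IAA29, SAUR19 and SAUR22) did the same, as did 6 of 7 cell wall loosening genes with PIF4ox, among them EXPA8, EXPA11, EXPA15, XTH4 and XTH17. PHYA and RGL1 were also lower in loss and higher in gain. Light harvesting and RuBisCO genes (LHCA6, RBCS1B, RBCS2B, RBCS3B and RCA) and the chlorophyll synthesis genes CHLI1, PCB2 and CHLG were higher in loss and lower in PIF4ox. The light harvesting list as a whole went the other way in the mutant, with 17 of 26 members lower and 6 higher. Of 1051 genes called in both loss and PIF4ox, 383 were lower then higher (189 if independent), 545 higher then lower (123), 66 lower in both and 57 higher in both. For PIF5ox the 717 genes split into 289 (138), 344 (61.8), 37 and 47. The correlation across genes was -0.19 for PIF4ox and -0.26 for PIF5ox among the called genes, and -0.10 and -0.14 over all genes.

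**Figure D4:**
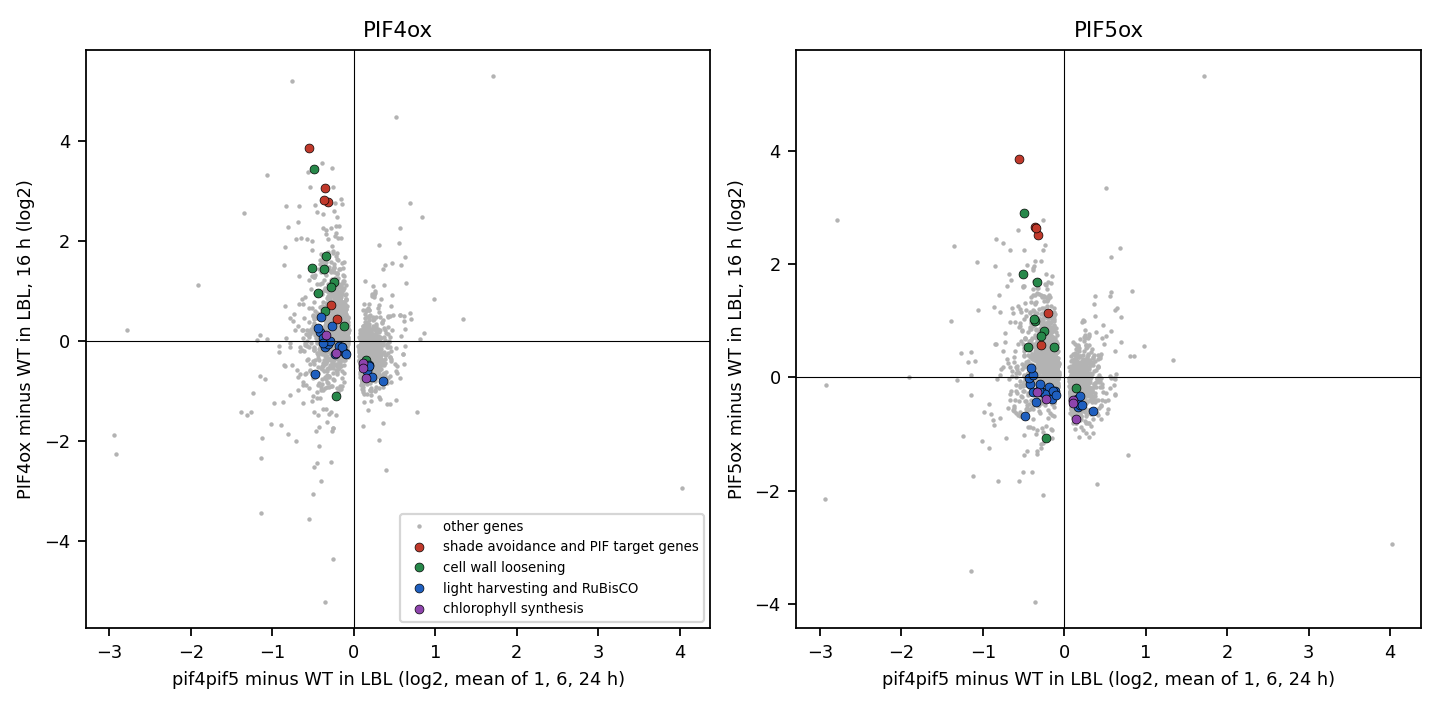
Log2 difference of pif4pif5 from WT in LBL (x, mean of 1, 6 and 24 h) against that of PIF4ox or PIF5ox from WT in LBL at 16 h (y), for the genes called in the mutant; coloured points are members of 4 lists. Of these genes 74.1% (PIF4ox) and 74.2% (PIF5ox) lie in the upper left and lower right quadrants.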

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

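The tests of a larger root share and of mislabelled libraries were chosen only after the result was seen. Differences between groups in the response to LBL drew attention in each interaction. The LBL response differed between pif4pif5 and WT in 419 genes at 1 h. It differed in 140 genes at 6 h. It differed in 337 genes at 24 h. Averaged over the times it differed in 622 genes. Between PIF4ox and WT at 16 h it differed in 105 genes. Between PIF5ox and WT it differed in 4 genes.

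Other groupings of the same libraries within each time and light were counted, 100 in all for each averaged result including the real one. For pif4pif5 against WT in WL, 3 of the 100, including the real one, gave as many genes as the real 971. The highest other gave 1217, and both others changed only the WL libraries of 6 h. One of them exchanged the genotypes fully at that time, and the other in part (a share of 0.5 of the libraries). The full exchange keeps the real groups, so it is not a random grouping. The genotype difference in WL at 6 h thus did not add to that of the other times, and the count rose without the 6 h libraries. In LBL only 1, the real one, gave as many as 2368, and the highest other gave 987. For the averaged interaction 2 of 100 did, including the real 622; the other gave 877 and exchanged the WL genotypes at 6 h and 1 library per genotype in WL at 1 and 24 h. The counts were thus 3, 1 and 2 of 100. In WL and for the averaged interaction another grouping gave more genes than the real one. These counts make chance less likely but do not exclude it.

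Of 14 root markers tested, 5 were called higher and 1 lower in PIF4ox than in WT in LBL at 16 h, while WT LBL replicate 2 was poor in root transcripts. The root hair markers COBL9, EXPA7 and RHD6 were near WT, at 0.029, 0.096 and -0.108. The set-test call of the root marker list was lost with the correlation estimated, with the smaller pseudocount and without the filter. Without WT LBL replicate 2 the median difference of the markers called higher kept 73.7% of its size (bootstrap interval over those markers 64.4 to 90.5). These markers were chosen with that library included, and WT then had 1 library. The interval thus does not measure the spread between libraries, and the share due to that library cannot be told. In PIF5ox against the same WT libraries, the median difference of called root markers fell from 1.38 to 0.70 without it. A larger share of root in the PIF4ox libraries would raise root types alike. The difference of CASP1, the smallest among the endodermal markers tested, exceeded the largest root hair difference by 2.15 log2 units. This goes against a larger root share alone. Without WT LBL replicate 2 the root hair markers COBL9, EXPA7 and RHD6 were at -0.54, -0.63 and -0.45. The line may thus change them itself, and the test cannot exclude a larger root share. Higher endodermal transcript levels as a response in PIF4ox stay a hypothesis, found and tested on the same data.

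Seed-type genes (M17, CRA1, PER1 and AtMT4b) were among the largest interactions at 6 h. M17 stood at 18.8 and 8.86 FPKM in the WT WL libraries and at 0.151 and 0.0467 in the pif4pif5 WL libraries. Seeds that had not germinated could raise them in some libraries; the further 11 seed genes had a median interaction of 0.117, with 7 above 0 and 0 of 4 tested genes called by limma, so the test cannot tell. At least 85.1% of the median interaction of M17, CRA1, PER1 and AtMT4b was kept without any 1 of the 8 libraries. These genes were picked for large calls in the same libraries, which makes such a result likely beforehand. The test thus does not exclude an effect of single libraries. A difference in seed-gene expression between the genotypes stays open.

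PIF4 was near WT in pif4pif5 and higher in PIF5ox. Reads that match both genes exactly do not explain it: 0 stretches of 31 bases were shared between the annotated transcripts of PIF4 and PIF5 (3 at 21 bases). Reads placed with mismatches were not examined. WT libraries labelled pif4pif5 by mistake do not either, since in 0 of them was PIF5 at or above the lowest WT library. The test cannot tell the double mutant from a line in which only PIF5 is altered, so other mislabelling stays open. Transcript made from the altered pif4 allele may remain in the count, and either PIF may raise the other's transcript. PIF5 was also higher in PIF4ox in WL, a call that ended without PIF4ox WL replicate 2 or WT WL replicate 2. In LBL PIF5 was not called in PIF4ox. Neither explanation was tested, and gene-level values cannot separate them.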

How the results depend on the processing

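Gene lists were tested under 5 alternatives, and none of their calls turned direction. Of 143 list calls in 399 tests, pseudocount 0.1 kept 139, no filter 140, median-ratio scaling 132, the replicate block 142 and the estimated correlation 25. Of 1071 called values of named genes, 1033, 980, 1006, 1022 and 1016 kept their call with pseudocount 0.1, no filter, scaling, the replicate block and no mean-variance trend; the separate fit of the compared groups kept 844 of 1047 and weakened 203. The mean, median and test of a list differed in sign in 61 tests, of which 0 were called by limma camera. With only 2 libraries per group and 16.0 to 40.3 M fragments each, small interactions are easily missed. Unless the alternative itself tests fewer libraries, the cause was not tested.

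The replicate numbers were not taken as pairs. The difference between the replicates of a group was correlated across genes with that of each other group of the same time. Not every such correlation was over 0.1 (-0.132 to 0.147 at 1 h, -0.0561 to 0.0259 at 6 h, -0.0121 to 0.115 at 24 h and -0.175 to 0.349 at 16 h, where 6 of 15 were). With the replicate block, interaction counts were 262 at 1 h, 221 at 24 h and 0 for PIF5ox, against 419, 337 and 4. Without the mean-variance trend they were 175, 207 and 12. For PIF5ox, pseudocount 0.1 gave 0 and protein-coding genes only, chosen after seeing the data, gave 24.

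A separate fit of the compared groups gave 1490 genes for LBL in WT at 1 h, 250 and 4990 in pif4pif5 at 1 and 6 h, and 6482 in WT at 16 h. It gave 22, 0 and 18 interactions at 1, 6 and 24 h, 446 for pif4pif5 in WL, 336 and 2219 for PIF5ox in WL and LBL, and 44 and 1 for the interactions of PIF4ox and PIF5ox. Averages without the 6 h libraries, chosen after seeing the data, gave 1549 interactions and 1662 and 1332 genes for pif4pif5 in WL and LBL, against 622, 971 and 2368. Without the libraries of low root markers, also chosen after, PIF4ox had 2638 genes in LBL, PIF5ox 222 in WL and 839 in LBL, and both interactions 0.

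Leaving out 1 library gave ranges of 1683 to 2139 for LBL in WT at 1 h and 1268 to 2080 in pif4pif5 at 1 h. For interactions they were 14 to 467 at 1 h, 5 to 232 at 6 h, 111 to 424 at 24 h, 324 to 763 averaged, 6 to 60 for PIF4ox and 0 to 58 for PIF5ox. For pif4pif5 in WL they were 411 to 1154; for PIF4ox in WL 915 to 2248 and in LBL 2461 to 4047; for PIF5ox in WL 113 to 639 and in LBL 624 to 2380. Other counts stayed within 1.5 times.

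Sign changes were in values that were not called, save 1. PIF4 with LBL in pif4pif5 at 1 h was -0.000124 under scaling and -0.111 to 0.141 without single libraries, below 0 without WL replicate 2 (-0.111) or LBL replicate 1 (-0.0297). The PIF5 interaction at 1 h was -0.230 to 0.0129, above 0 without pif4pif5 WL replicate 1. At 24 h it was -0.0613 to 0.137, below 0 without pif4pif5 LBL replicate 2 or WL replicate 1 (-0.000277). PIF5 with LBL in PIF4ox was -0.328 to 0.519, below 0 without PIF4ox WL replicate 1. AtMT4b, called for the averaged interaction, was -0.0763 without the 6 h libraries.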

Other observations

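Further list results outside the report follow. In PIF4ox against WT in WL, photoreceptors were higher in 4 of 13 (adjusted p = 0.0026) and cell wall loosening genes in 10 of 21 with 1 lower (0.025), with EXPA8 at 1.86. The stomatal lineage (0.0053) and cell cycle (0.013) lists were lower with 0 of 7 and 0 of 13 called by limma, and light harvesting with 2 of 26 (0.00013). With an estimated correlation these stood at adjusted p = 0.23, 0.34, 0.34, 0.53 and 0.34. In PIF5ox in WL, jasmonate genes were higher in 2 of 13 and 9 over the list alone (6.5e-06), brassinosteroid genes in 3 of 16 (0.0013) and photoreceptors in 3 of 13 (0.0015), while light harvesting genes were lower in 2 of 26 (2.3e-05). These stood at adjusted p = 0.23, 0.30, 0.28 and 0.40 with an estimated correlation.

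At 24 h the LBL response of starvation genes was larger in pif4pif5 as a list (adjusted p = 0.017; 0.44 with an estimated correlation), with 0 of 16 members called by limma. At 1 h the stomatal lineage list had a negative interaction (0.026; 0.38 with an estimated correlation; 3 of 7 over the list alone). In the PIF5ox interaction, brassinosteroid (0.00025; 0.36 with an estimated correlation) and cell cycle (0.0004; 0.53) lists had a positive and a negative set test, with 0 of 16 and 0 of 13 members called by limma. With LBL in WT at 24 h, BOA, an evening clock gene, rose by 1.71 and LHY, a morning clock gene, fell by 0.96, and MUTE, a stomatal gene, fell by 0.81.

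CYP97B3, a carotenoid hydroxylase relative, lay between 8.40 and 9.94 FPKM in the groups of PIF4ox and PIF5ox and at 59.1 and 58.0 in WT at 16 h, in both lights. Genes that moved the same way in pif4pif5 and both gain lines in both lights, chosen after their values were seen, were 1 higher (AT2G43018) and 6 lower (ACL, AT2G32870, SADHU3-2, PRXCB, ChiC and BGLU47). SADHU3-2, a transposon-derived locus, was lower by -2.60 and -2.94 in pif4pif5 in WL and LBL. Plastid-encoded transcripts made up 0.222% to 0.725% of FPKM, highest in replicate 1 of pif4pif5 in WL at 6 h.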
